A study of Sporobolus maritimus and Sporobolus alterniflorus and Sporobolus x townsendii with 20 samples.

How the data were processed

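Total RNA from young leaves of 4 kinds of cordgrass (Spartina) was measured on 20 one-colour Agilent rice oligonucleotide arrays, 5 arrays per kind. Per the labels' protocols, all plants were grown under one regime, and 350 ng of total RNA per sample was amplified and labelled with the dye Cy3. The labels name S. maritima as the paternal parent, S. alterniflora as the maternal parent, the F1 hybrid (written S.x towensendii there) and the allopolyploid S. anglica. They do not say that the 5 arrays of a kind came from separate plants, so p-values measure only the spread between these samples, which may be technical.

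The deposited scanner files hold spot intensity on a linear scale, already background-subtracted by Agilent Feature Extraction, version 9.5.1.1 per the file headers and version 9.1 per the submitters' processing notes. No scaling between arrays is recorded in the file headers, and spots below background can be negative. Each array carried 21495 rice probes with 2 spots per probe, and each probe is named by a rice cDNA. The descriptions in the files name the best database match of that cDNA, often a gene of another species, so a description is a likeness and not an identification in Spartina. Probes were designed on rice and hybridised with Spartina RNA, so a difference in how well a probe matches each species can produce a difference in signal without a difference in transcript level. No genome or probe annotation was used here beyond the files, and no coordinates are given.

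A second deposited table holds log2 values of the same arrays. Set against the scanner intensity of each array, these log2 values from the authors were log2 of the processed signal, with a minimum of 1, minus the median of each array. The slope was close to 1 and the column medians were close to 0. Probe by probe, after centring, each column correlated with its own array at r = 0.988 to 1.000 (0.99979 at most), so direction and scale were settled from the values. The source of that median subtraction is not given in the sources used here. The median processed signal was 4.41 on S. maritima 2 and 1.37 on S. alterniflora 2, and under the minimum of 1 on all other arrays. Against the values used here, the median probe-centred difference of the table was -1.84 on S. maritima 2. It was -0.28 to 0.36 on the others, so the table set S. maritima 2 lower. The table was used as an alternative only.

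Control spots and spots flagged by Feature Extraction as non-uniform or population outliers were left out, and the remaining spots of a probe were averaged. Most probes were not well above background, so each array was scaled to the 75th percentile of the 879 probes well above background on all 20 arrays. A floor of 6.78 scaled units, the median over arrays of the lowest signal well above background, was set after scaling and before log2. Probes well above background on at least 4 of the 5 arrays of at least 1 group were tested. These were 1778 probes, of which 10 lacked a value, leaving 1768. Of these, 685 had a description naming a product and 1083 had none. The pattern that separates named from unnamed descriptions was adjusted after the descriptions were read. Precision is limited by the number of arrays. The self-test on simulated data, with 200 of 1768 probes changed, recovered 52.6% of 2-fold changes between the parents, 65.8% for the hybrid against the midparent, 66.8% for S. anglica against the midparent and 54.6% for S. anglica against the hybrid. Of changes of 1.5-fold, it recovered 16.4%, 29.0%, 26.6% and 16.2% in the same order.

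Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 20 arrays with a mean for each of the 4 groups, and Benjamini-Hochberg adjustment over the 1768 probes. A probe passed at an adjusted p under 0.05. Every adjusted p of a probe below comes from this limma fit, and errors of log2 differences are standard errors. The midparent is log2 of the mean of both parental group means on the linear scale, since RNA of an additive hybrid is a linear mixture. Its error was obtained by the delta method with limma's posterior variance. In data simulated with unchanged probes at the linear midparent, a log-scale midparent gave 40.7% false calls for the hybrid and 41.1% for S. anglica. The linear one gave 3.85% and 4.69%. Since the simulation assumed the linear scale, these shares do not decide which scale holds in the plants. A probe was called transgressive where it differed in the same direction from both parents. The position of an array between the parents is the median, over probes that differed between the parents by at least 1 log2 unit, of its distance from the S. maritima mean as a share of the parental difference. It was taken for each direction and averaged, so that 0 is the paternal and 1 the maternal level. Positions and set scores were compared by exact permutation tests, two-sided, for which 5 arrays against 5 allow a smallest p of 0.00794. With a block they were compared in a linear model of group and block, since arrays are then not free to exchange.

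A probe below background on every array of one group has only a bound there. Its fold is given as "at least" the bright group's mean over the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own floored signal, both means on the log2 scale. Where a group was well above background on only 1 or 2 arrays, the size of a log2 difference depends on the floor. Named genes followed a rule fixed before the data were examined, as were the comparisons, the gene lists and most alternatives. In each main comparison these were the 6 largest rises and 6 largest falls among probes that passed, were well above background on all arrays compared, had arrays that did not overlap (against the midparent, all arrays of the group on one side of that single value) and had a named product. The member of each gene list with the smallest adjusted p in each direction was added, and for the parents also the pair of largest bounds in each direction. Genes outside this rule are said to be so where they appear. The 21 gene lists are word patterns on the descriptions, so members can be caught by a word alone. The thionin pattern, for example, also matches methionine aminopeptidase. Of the lists, 20 had a measured member and 16 had enough for limma's cameraPR, which was run with a preset correlation of 0.01 and again with an estimated correlation.

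Slides and scan days were read from the files and are numbered here. The arrays lay on 7 slides, and no slide held all 4 groups. S. maritima 3 and 4 shared slide 1 with S. anglica 1 and 4. Slide 2 held S. alterniflora 3 and 4 alone, and slide 3 held S. maritima 5, S. alterniflora 2 and S. anglica 2. Hybrid 4 shared slide 4 with S. anglica 3 and 5, hybrid 3 lay on slide 5, and slides 6 and 7 held both parents with the hybrid. Each comparison was refitted with slide as a block and repeated within the slides that held its groups. Other alternatives were other scalings (the percentile over all probes, the median, quantile normalization), normexp with an offset of 50 on mean signal and background, the authors' table, other filters, scan day or replicate number as a block, other thresholds and leaving out each array. The floor halved or doubled, other background subtractions, leaving out 4 arrays that stood apart and leaving out slide 7 were added after the data were seen. The 3 sets of organelle-related transcripts in the closing section were also defined after the data were seen.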

Results

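The study asked how gene expression changed when the genomes of different Spartina species came together in a hybrid, and how it changed again when that hybrid genome was duplicated. Leaf RNA of both parents, S. maritima (paternal) and S. alterniflora (maternal), of their F1 hybrid and of the allopolyploid S. anglica was hybridised to rice arrays, with 5 arrays for each of the 4 groups. The labels give the parents and the hybrid as hexaploid and S. anglica as dodecaploid. Between 6.72% and 17.1% of spots were well above background, apart from S. maritima replicate 2 with 32.7%. Of 21495 probes, 1768 were bright enough to test, and 1027 of these were well above background on at least 4 arrays in all 4 groups. By the same criterion 1473 probes were measured in S. maritima, 1245 in S. alterniflora, 1487 in the hybrid and 1364 in S. anglica.

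Arrays of one group resembled each other more than arrays of different groups. Across tested probes, which are not independent replicates, the median correlation within a group was 0.963 in S. maritima, 0.969 in S. alterniflora, 0.966 in the hybrid and 0.967 in S. anglica. Between the parents it was 0.853. The hybrid correlated at 0.940 with S. alterniflora and at 0.910 with S. maritima, and S. anglica at 0.918 and 0.890. The first principal component held 38.9% of the variance and placed every hybrid and S. anglica array between those of the parents. The second held 21.9%, and S. anglica 3, 4 and 5 lay highest on it.

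**Figure D1:**
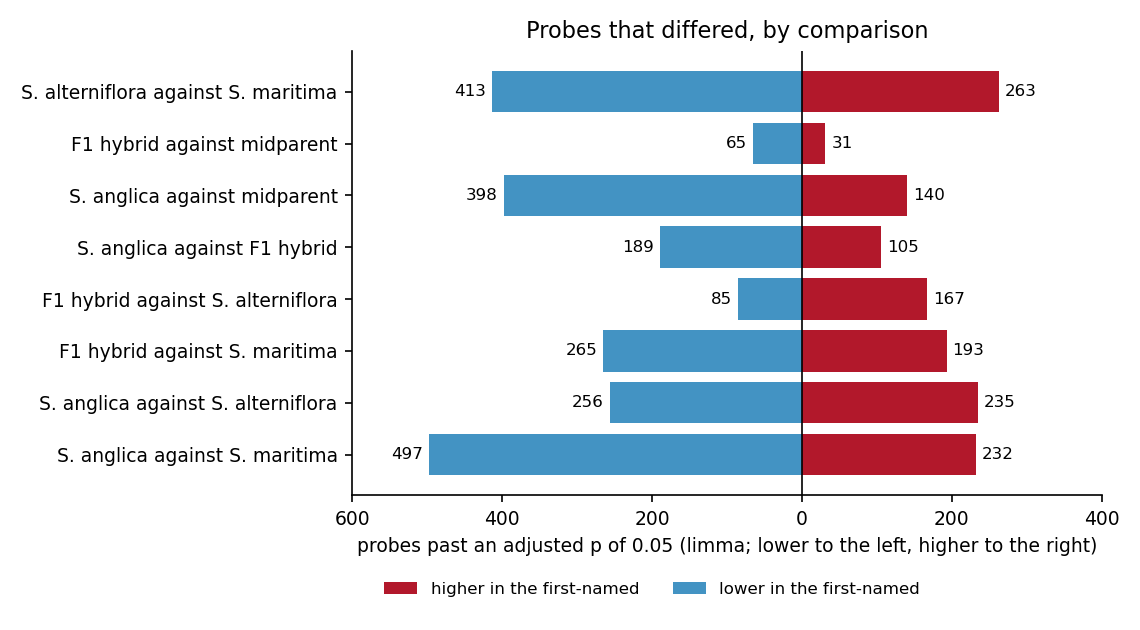
Bars give the number of probes past an adjusted p of 0.05 in limma for each of 8 comparisons, on 5 arrays per group, with probes lower in the first-named group to the left and higher ones to the right. The parents differed at 676 probes (263 of them higher in S. alterniflora), the hybrid departed from the midparent at 96 and S. anglica at 538.

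The parents were compared first, since they set the range in which a hybrid can lie. S. alterniflora gave far more signal than S. maritima for a chitinase (AK062114), an enzyme that degrades chitin of fungal walls, with a log2 difference of 6.41 ± 0.41 or 84.9-fold (adjusted p = 9.63e-11). A phytochelatin synthetase-like protein (AK060897, 6.13 ± 0.60, adjusted p = 3.89e-08) and a chlorophyll a/b binding protein of the light-harvesting antenna (AK066762, 6.03 ± 0.43, adjusted p = 4.37e-10) followed. Higher in S. maritima were a basic helix-loop-helix transcription factor (AK107555, -4.04 ± 0.35, adjusted p = 6.57e-09) and PCNA, the sliding clamp of DNA replication (AK071591, -3.72 ± 0.22, adjusted p = 2.49e-11). In all, 676 of 1768 probes (38.2%) differed, 263 of them higher in S. alterniflora and the others in S. maritima, and 482 by at least 2-fold.

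The other large differences included sucrose synthase 3, which splits sucrose for use in sink tissues (AK099406, 5.11), a lysyl-tRNA synthetase (AK110356, 5.08) and a prefoldin (AK059656, 4.45), all higher in S. alterniflora. The probes of the lysyl-tRNA synthetase, the chitinase, the phytochelatin synthetase-like protein and the chlorophyll a/b binding protein varied together between arrays. Each was lowest on replicate 1 and highest on replicate 2 in S. maritima, and lowest on replicate 3 and highest on replicate 2 in S. anglica. Whether they read separate transcripts was not tested. A copia retroelement polyprotein (AK108737, -3.46), the beta subunit of pyrophosphate-dependent phosphofructokinase (AK069095, -3.33), a copper amine oxidase (AK105824, -3.30) and a selenium-binding protein (AK072084, -2.87) were higher in S. maritima. Some transcripts were seen in 1 parent only. In S. alterniflora, 20 probes were well above background on all 5 arrays and on no S. maritima array, and 36 probes showed the opposite. Among them CRP1, which acts in the processing of chloroplast RNA (AK066480), was at least 21.55-fold higher in S. alterniflora (adjusted p = 9.16e-13), although another probe described as CRP1 was lower there (-1.06). A PP2A regulatory subunit (AK108850) was at least 12.3-fold higher in S. alterniflora. Monooxygenase 2 (AK106420) was at least 14.3-fold and a calcium-dependent protein kinase (AK068414) at least 6.54-fold higher in S. maritima.

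Genes tied to life in salt marshes moved both ways between the parents. Of 7 measured members of the ion transport list, 3 were higher in S. alterniflora, among them the potassium transporter hak1 (AK070831, 2.79 ± 0.30, adjusted p = 1.25e-07). The sodium/proton antiporter NHX1 (AK066168), which loads sodium into the vacuole, was 1 of 2 members higher in S. maritima (-2.22 ± 0.30, adjusted p = 3.65e-06) and was well above background on only 1 S. alterniflora array. Betaine aldehyde dehydrogenase, which makes the osmoprotectant glycine betaine (AK071221), was higher in S. alterniflora by 1.06 ± 0.21 (adjusted p = 0.000347). In the dehydration list of 10 members, 2 were higher and 2 lower, the early drought induced protein R1G1A (AK066832) at -0.60 among the latter. The 11 aquaporin probes of the array were too dim for a test.

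In photosynthesis, the Rubisco large subunit rbcL (AK058516) was higher in S. alterniflora by 2.67 ± 0.38 (adjusted p = 6.87e-06) as was 1 other of the 4 Calvin cycle members. Glutamyl-tRNA reductase, the first committed enzyme of tetrapyrrole synthesis (AK099393), was higher by 1.63 ± 0.27. The plastidic aspartate aminotransferase (AK072426, -1.07) was among 2 of 4 C4 enzymes lower in S. alterniflora. Of 8 photosystem members, 1 was higher and 1 lower, and the lower one, the photosystem I antenna protein Lhca (AK104283, -1.57, adjusted p = 0.0439), passed neither over the list alone nor with slide as a block (adjusted p = 0.269 in the latter).

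Of 10 chaperones, 7 were lower in S. alterniflora and 1 was higher (8 and 1 adjusted over the list alone), with a chaperonin (AK065883) at -1.87 ± 0.17 and the superoxide dismutase copper chaperone CCS (AK065277) at 1.20 ± 0.35. The median was -1.21, and -1.01 or below under every scaling tried, but the list did not pass as a whole (cameraPR adjusted p = 0.415). Of 25 cell wall genes, 9 were lower, with a xyloglucan endoglucanase inhibitor (AK070554) at -5.62 ± 0.68 but well above background on only 1 S. alterniflora array, and 1 was higher, the leucine-rich repeat extensin LRX1 (AK105732) at 4.56 ± 0.49. Of 26 ubiquitin and proteasome genes, 5 were higher and 9 lower. UBP22 (AK100969) was at least 4.95-fold higher in S. alterniflora and a ubiquitin conjugating protein (AK112003) lower by -1.84. Of 13 hormone genes, 5 were higher and 1 lower (6 and 1 adjusted over the list alone), with the auxin-regulated IAA8 (AK109363) at 3.35 ± 0.22 and cytokinin dehydrogenase 2 (AK103272) at -1.67 ± 0.42, the latter well above background on 1 S. alterniflora array and with an adjusted p of 0.0604 under a slide block.

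Of 9 antioxidant genes, 4 were higher and 3 lower, with glutaredoxin (AK058431) at 1.31 and peroxiredoxin (AK058509) at -2.59. Of 9 defence genes, 2 were higher and 1 lower, a beta-glucanase (AK058891) at -5.41, well above background on only 1 S. alterniflora array. Of 9 cell cycle genes, 1 was higher, cyclin delta-3 (AK100123) at 1.05, and 3 were lower. Argonaute AGO1 (AK060907), the core protein of RNA silencing, was at -1.08 and was the 1 of 2 silencing genes that passed. Ribosomal protein L34 (AK059470) was at -2.13, the phytochrome signalling gene spa1 (AK101974) at 2.74 with 1 S. maritima array well above background, cryptochrome 1a (AK064910) at -0.46 and a nodulin N21-like protein (AK068810) at 1.84. Of 5 common reference genes, 1 was higher, actin (AK060893) at 2.14 ± 0.23, and 2 were lower (3 adjusted over the list alone), with tubulin cofactor B (AK102150) at -0.81. The 2 senescing-leaf markers did not pass. No gene list shifted as a whole in any of the 4 main comparisons. The smallest adjusted p of cameraPR was 0.392 over 64 tests, of which 7 had an unadjusted p under 0.05, and 0.989 with an estimated correlation.

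Under a slide block, 671 probes differed between the parents (271 higher and 400 lower in S. alterniflora), 591 of them the same probes in the same direction. Within slides 3, 6 and 7, which held both parents, 97.9%, 94.4% and 98.1% of the 676 had the same direction. The share of probes higher in S. alterniflora was 38.9%, and moved to 49.5% under quantile normalization, 59.5% in the authors' table and 24.8% under normexp.

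**Figure D2:**
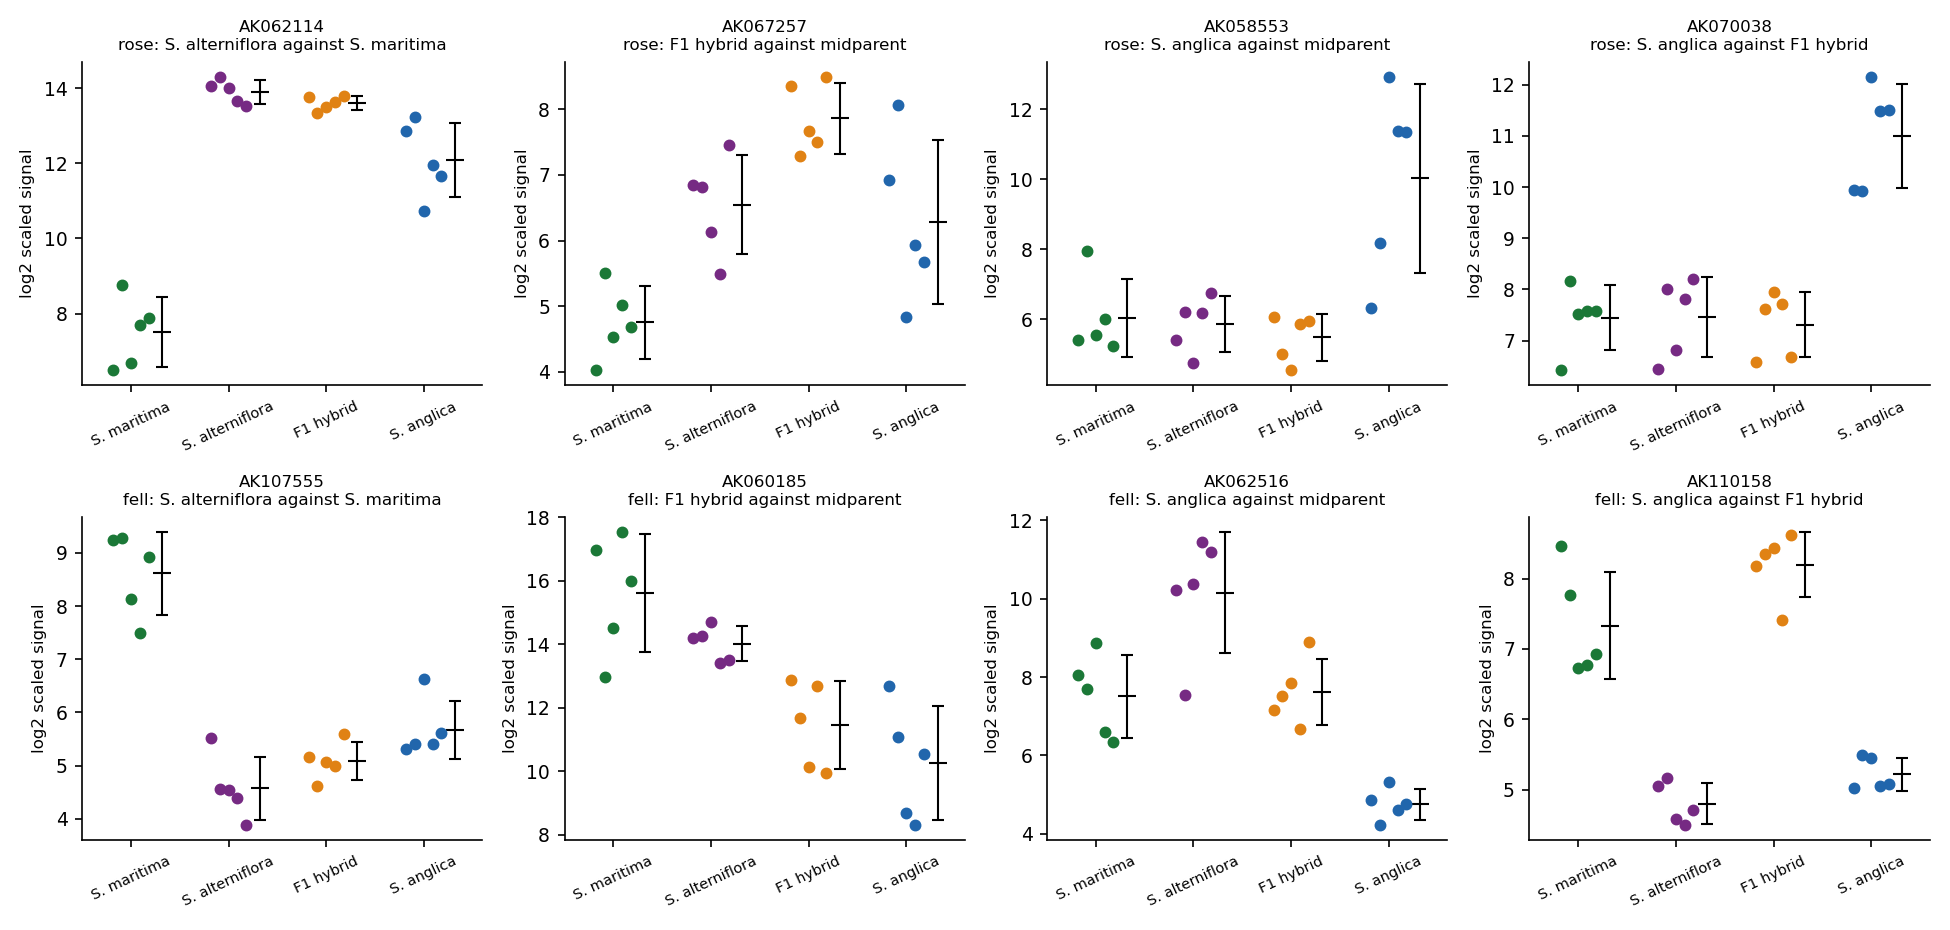
Each panel shows the log2 scaled signal of 1 probe on all 20 arrays (points), with mean and SD over 5 arrays per group beside them, for a gene among the largest rises (upper panels) and falls (lower panels) of each main comparison. The asparaginyl endopeptidase AK058553 averaged 10.03 in S. anglica and 5.49 in the hybrid, and the AFG3-like protein AK110158 averaged 8.20 in the hybrid and 5.22 in S. anglica.

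The hybrid was then set against the midparent, the level an even mixture of both parental RNAs would give. A Bowman-Birk proteinase inhibitor, a defence protein against digestive enzymes (AK067257), was above it by 1.95 ± 0.43 (adjusted p = 0.0116), as were the nodulin N21-like protein (AK068810, 1.87 ± 0.43, adjusted p = 0.0143) and an AFG3-like ATPase, a relative of mitochondrial proteases (AK110158, 1.64 ± 0.28, adjusted p = 0.00137). The transcription factor AK107555 was below it by -2.61 ± 0.34 (adjusted p = 8.78e-05), close to its low S. alterniflora level. Transcripts described as mitochondrial were also low, namely ribosomal protein gene rps3 (AK064438, -1.36 ± 0.17, adjusted p = 8.78e-05), the large ribosomal RNA (AK061547, -1.35 ± 0.26, adjusted p = 0.00461) and subunit 1 of NADH dehydrogenase (AK064531, -1.21 ± 0.32, adjusted p = 0.0300). In all, 96 probes (5.43%) departed from the midparent, 31 above and 65 below, and 65 of them by at least 2-fold.

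The largest fall was that of a chloroplast ribosomal RNA (AK060185, -3.56 ± 0.76, adjusted p = 0.00907), which lay below both parents but varied widely between arrays and had an adjusted p of 0.130 with slide as a block. A seed storage protein of the coixin type (AK106275, -1.26 ± 0.19, adjusted p = 0.000387) was also below both parents. The AFG3-like ATPase was above both by group means, although S. maritima 1 and 2, at 8.47 and 7.77, lay among the hybrid arrays. Further rises were an endoglucanase (AK103304, 1.34 ± 0.36, adjusted p = 0.0306), PGPD14 (AK104810, 1.18) and dehydrin, a protein of dehydrated tissue (AK109096, 1.12). The last 2 did not pass with slide as a block (adjusted p = 0.0707 and 0.134), nor did the NADH dehydrogenase subunit (0.0651).

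Of the 21 lists, 7 held a member that passed. The ethylene-responsive ebp-89 (AK073133) was at 2.08 ± 0.49 (adjusted p = 0.0149) and was the 1 hormone gene that rose. A Skipper-like gag sequence (AK062058) was the 1 transposable element that rose, at 1.55 ± 0.39, with an adjusted p of 0.0773 under a slide block. Cellulose synthase 8 (AK100914) was the 1 cell wall gene that fell, at -0.62 (adjusted p = 0.0530 under a slide block), and actin (AK060893) the 1 reference gene, at -0.73 (adjusted p = 0.257 with slide as a block). Adjusted over the list alone, 2 members each of the C4 and ion transport lists, 1 member each of the Calvin cycle, dehydration and hormone lists and 1 other reference gene also fell.

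Under a slide block, 92 probes departed from the midparent, of which 51 were the same probes in the same direction, and within slides 6 and 7 the direction held for 92.7% and 100% of the 96. The count fell to 40 without hybrid replicate 5, 56 without replicate 3, 60 without replicate 1 and 30 without 4 arrays that stood apart, and the share above the midparent (32.3%) was 77.5% in the authors' table, 89.5% with the percentile over all probes, 42.9% under normexp and 69.1% with a log-scale midparent.

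**Figure D3:**
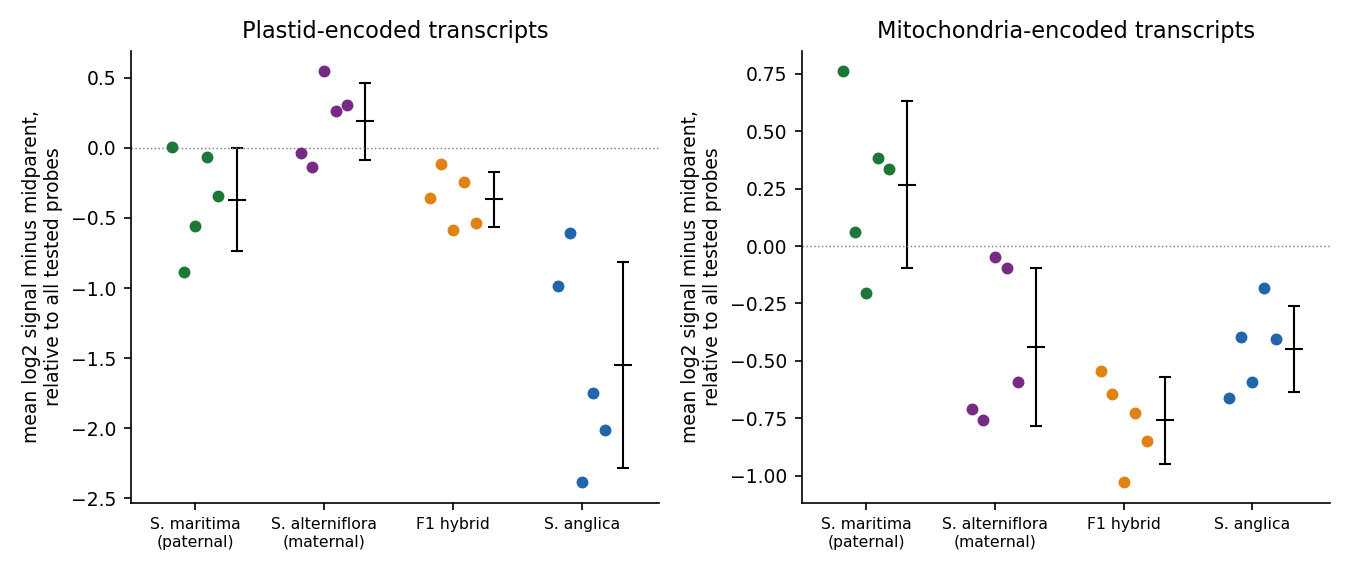
Points give, for each of 20 arrays, the mean over a set of transcripts of log2 signal minus the midparent, relative to all tested probes, with mean and SD of 5 arrays beside each group; the 21 plastid-encoded probes are on the left and the 9 mitochondria-encoded ones on the right, both sets chosen after the data were seen. The S. anglica arrays averaged -1.55 for plastid transcripts against -0.37 in the hybrid, and the hybrid averaged -0.76 for mitochondrial transcripts against 0.27 in S. maritima.

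S. anglica departed from the midparent at many more probes, many transcripts of the plastid genome among the falls. They included the RNA polymerase subunit rpoC2 (AK062380, -2.66 ± 0.25, adjusted p = 2.88e-07), the photosystem I assembly factor ycf4 (AK062797, -2.62 ± 0.29, adjusted p = 1.69e-06), cytochrome f petA (AK110705, -2.45 ± 0.25, adjusted p = 5.33e-07) and the chloroplast ribosomal RNAs AK060185 (-4.77 ± 0.76, adjusted p = 0.000122) and AK059621 (-2.80 ± 0.37, adjusted p = 1.57e-05). An asparaginyl endopeptidase, of the family of vacuolar processing enzymes, rose 16.9-fold (AK058553, 4.08 ± 0.76, adjusted p = 0.000444), though its 5 arrays ran from 6.32 to 12.92. The elicitor-responsive ACRE132 (AK070038, 3.55 ± 0.39, adjusted p = 1.69e-06) and a lipid transfer protein (AK063196, 3.23 ± 0.41, adjusted p = 8.67e-06) rose on all arrays. For each of the genes just named, S. anglica 1 and 2 lay nearer the midparent than replicates 3 to 5. The lipid transfer protein, for example, stood at 5.77 and 6.53 on the former and at 7.78 to 9.59 on the latter. In all, 538 probes (30.4%) departed, 140 above and 398 below, and 243 of them by at least 2-fold.

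Each of these 8 genes differed from both parents in the same direction by group means, although S. anglica 1, at 6.32 for the endopeptidase (AK058553), lay among the parental arrays. So did S. anglica 2 for the chloroplast ribosomal RNA AK059621, at 13.61 beside 13.56 and 13.36 on S. maritima 3 and 4. Also different from both in group means were a protein kinase (AK070965, 1.65 ± 0.25), a peroxisomal membrane protein (AK100851, 1.64 ± 0.23) and the chloroplast nucleoid protease CND41 (AK105666, 1.84 ± 0.45), all above, the last with an adjusted p of 0.153 under a slide block. All of these were higher on S. anglica 3 to 5 than on replicates 1 and 2. A Gip1-like protein (AK062516) fell below both parents by -4.61 ± 0.56 against the midparent (adjusted p = 5.57e-06).

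In photosynthesis, the median of 8 photosystem members against the midparent was -1.17 and that of 4 Calvin cycle members -1.69. Both were negative under every scaling tried, at most -0.36 and -0.06, but neither list passed as a whole (cameraPR adjusted p = 0.415 for each). Of the 8 photosystem members 4 fell (6 adjusted over the list alone), among them the plastid genes psbM (AK058861, -2.39 ± 0.41, adjusted p = 0.000211) and psaB (AK059927, -2.68, adjusted p = 0.00066), the latter outside the naming rule. Of the 4 Calvin cycle members 3 fell, namely ribulose phosphate epimerase (AK064675, -1.48 ± 0.23, adjusted p = 8.72e-05) and, with larger falls outside the naming rule, both rbcL probes of the plastid genome (AK058516, -1.99, and AK058623, -1.89, the latter well above background on 1 S. anglica array). Phosphoenolpyruvate carboxykinase of the C4 pathway (AK102392, -1.77 ± 0.35, well above background on 2 S. anglica arrays) and glutamyl-tRNA reductase (AK099393, -1.82 ± 0.24) also fell.

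In the cell wall, cell cycle, dehydration, ubiquitin and hormone lists most members did not pass against the midparent. The medians of the first 3 were -0.60, -0.66 and -0.61, beside -0.35 for all tested probes. Of 25 cell wall genes 6 fell, among them the beta-expansin EXPB6, a wall-loosening protein (AK101728, -3.45 ± 0.75, adjusted p = 0.00176, well above background on 2 S. anglica arrays). Of 9 cell cycle genes 4 fell, among them cyclin delta-3 (AK100123, -1.24). Of 10 dehydration genes 3 fell, among them betaine aldehyde dehydrogenase (AK071221, -1.15 ± 0.19, adjusted p = 0.000139), and the potassium transporter AtKT2 (AK070738) fell by 1.16, the 1 ion transport gene that passed (4 adjusted over the list alone). AGO1 (AK060907, -1.10), the copia element (AK108737, -1.28), an IAA8-like gene (AK063854, -1.24), the cysteine protease SPCP1 (AK110832, -1.02) and actin (AK060893, -1.60 ± 0.21) fell as well. Of 9 antioxidant genes 3 fell, peroxiredoxin (AK058509) by 1.42, and 2 rose, among them thioredoxin h (AK059196, 0.96, adjusted p = 0.0650 under a slide block). A nodulin-type protein (AK073339) rose by 2.18 ± 0.57. Of 26 ubiquitin and proteasome genes 6 fell and 3 rose (6 and 4 adjusted over the list alone), among the latter polyubiquitin (AK067024, 0.91, adjusted p = 0.272 under a slide block), and of 13 hormone genes 2 fell and 1 rose (1 and 0 adjusted over the list alone), cytokinin dehydrogenase 2 (AK103272, 1.03, adjusted p = 0.224 under a slide block). Smaller falls of ribosomal protein L34 (AK059470, -0.77), a heat shock protein (AK101973, -0.80), a class III chitinase (AK058882, -0.70) and the proteasome subunit PAG1 (AK061784, -0.61) changed sign when arrays were scaled by the percentile over all probes, which moved the median of all tested probes to 0.37, and that of L34 did not pass with slide as a block (adjusted p = 0.0792).

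A slide block gave 817 probes that departed from the midparent (145 above and 672 below), 459 of them the same probes in the same direction, and within slide 3 the direction held for 97.4% of the 538. The median over all tested probes lay at -0.35, and the share above the midparent (26.02%) was 41.8% under quantile normalization, 39.3% under median scaling, 57.3% in the authors' table, 88.4% with the percentile over all probes and 38.2% with a log-scale midparent.

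S. anglica was set directly against the F1 hybrid, which shares its parents but not the duplicated genome. The asparaginyl endopeptidase (AK058553, 4.54 ± 0.88, adjusted p = 0.00175), ACRE132 (AK070038, 3.70 ± 0.45, adjusted p = 2.02e-05) and the lipid transfer protein (AK063196, 2.57 ± 0.47, adjusted p = 0.00105) were higher in S. anglica. The AFG3-like ATPase (AK110158) was lower by -2.98 ± 0.30 (adjusted p = 1.48e-06), with S. anglica at the low S. alterniflora level and the hybrid mean above both parental means. rbcL (AK058516), at 9.61 in the hybrid and 10.08 in S. alterniflora, averaged 7.29 in S. anglica and 7.41 in S. maritima (-2.32 ± 0.38 against the hybrid, adjusted p = 0.000404), but S. anglica 1 and 2 stood at 8.52 and 8.44 and replicates 3 to 5 between 6.43 and 6.60. In all, 294 probes (16.6%) differed, 105 higher and 189 lower in S. anglica, and 191 by at least 2-fold.

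The plastid genes ycf4 (AK062797, -2.36 ± 0.33, adjusted p = 0.000101), psbM (AK058861, -2.27 ± 0.46) and petA (AK110705, -2.11 ± 0.29, adjusted p = 6.94e-05) and the Gip1-like gene (AK062516, -2.86 ± 0.60) were lower than in the hybrid. So were 4 of 8 photosystem and 2 of 4 Calvin cycle members (4 and 3 adjusted over the list alone), glutamyl-tRNA reductase (AK099393, -1.78), the cold acclimation protein COR413 (AK065748, -1.53), cyclin delta-3 (AK100123, -1.31) and the chitinase that set the parents apart (AK062114, -1.52). Of 25 cell wall genes 5 fell (6 adjusted over the list alone), and 2 ribosomal protein genes and 2 senescing-leaf markers did so only over their list alone. Phosphoenolpyruvate carboxylase, the first carbon-fixing enzyme of the C4 pathway (AK101274), was higher by 1.27 ± 0.32 (adjusted p = 0.0104). Cytokinin dehydrogenase 2 (AK103272), which degrades cytokinins and was not well above background on any hybrid array, was at least 4.26-fold higher in S. anglica (adjusted p = 0.00175).

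Polyubiquitin (AK067024, 1.65 ± 0.32), the nodulin-type protein AK073339 (2.56 ± 0.65), the protein kinase AK070965 (1.28) and the peroxisomal membrane protein AK100851 (1.25) were higher as well. Lower were peroxiredoxin (AK058509, -1.03), a heat shock protein (AK101973, -0.81), AtKT2 (AK070738, -0.78), actin (AK060893, -0.87) and PAG1 (AK061784, -0.55), the last with the opposite sign under the percentile over all probes. Of the genes above the midparent in the hybrid, ebp-89 (AK073133, -1.70), the nodulin N21-like protein (AK068810, -1.62) and the Skipper-like sequence (AK062058, -1.38) were lower in S. anglica, but these 3 and a cellulose synthase (AK067850, -0.98) did not pass with slide as a block (adjusted p = 0.134, 0.181, 0.129 and 0.0684).

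With slide as a block, 412 probes differed (136 higher and 276 lower), 223 of them the same probes in the same direction, and within slide 4 the direction held for 98.98% of the 294. The count was 194 without S. anglica replicate 3 or without replicate 4, and the share higher in S. anglica (35.7%) was 53.4% under quantile normalization, 54.8% under median scaling and 90.9% with the percentile over all probes.

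Against single parents, the hybrid differed from S. alterniflora at 252 probes (167 higher and 85 lower) and from S. maritima at 458 (193 and 265). S. anglica differed from S. alterniflora at 491 probes (235 and 256) and from S. maritima at 729 (232 and 497). Under a slide block the totals were 198, 535, 503 and 1072. Of the 676 probes that set the parents apart, 277 (41.0%) differed in the hybrid from S. maritima only, and 90 (13.3%) from S. alterniflora only, while 183 differed from neither. In S. anglica these were 300 (44.4%), 150 (22.2%) and 69. In the hybrid, 19 probes lay outside both parents, 11 above and 8 below, of which 2 were among the 8 found with slide as a block. In S. anglica 157 did, 64 above and 93 below, and 113 of them were among the 257 found with slide as a block. The chloroplast ribosomal RNA AK060185 and the coixin-type AK106275 lay below both parents in hybrid and S. anglica alike, and were among 11 probes outside both parents in both (5 above and 6 below). Independent lists would share 0.398 above and 0.421 below, but both lists rest on the same parental arrays. Simulated groups set to the midparent shared at most 1. Since those groups had no true departures, they do not show how many probes lists of 19 and 157 would share through errors of the parental means.

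Both departures from the midparent rest on the same parental arrays. Across probes they correlated at r = 0.417, within the range of simulated groups without effects (median 0.368, highest 0.431), and at 0.296 when each departure was given its own parental arrays, and their covariance was 0.148 against a simulated 0.0326 (highest 0.0416), a difference of 0.115. Below the midparent in both were 46 probes, and above it in both were 8, with 4 in opposite directions. Independent lists of these sizes would share 14.6, 2.45 and 12.1. Split parents gave medians of 13.5, 4 and 1.5, but from fits with fewer parental arrays, for which the sharing of independent lists was not computed.

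**Figure D4:**
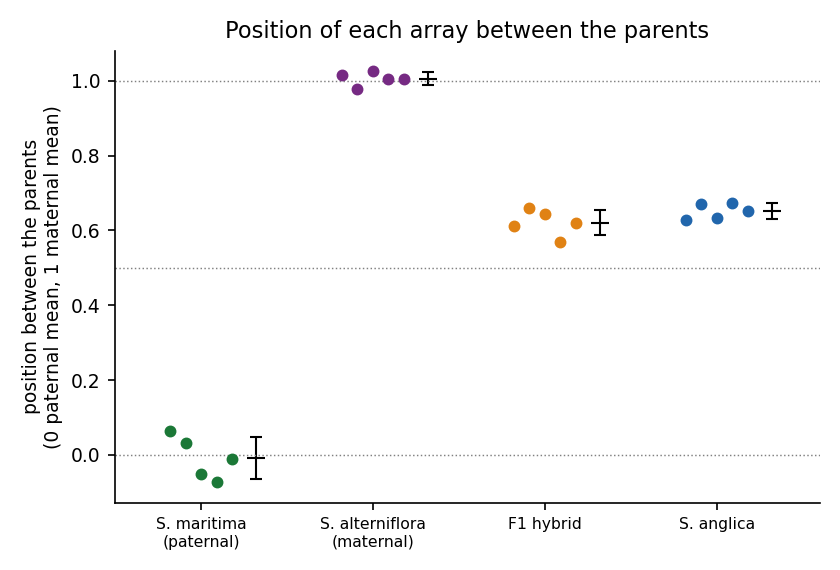
Points give the position of each of the 20 arrays between the parental means (0 is the S. maritima mean and 1 the S. alterniflora mean) over 482 probes, with mean and SD of 5 arrays beside each group. Every hybrid array lay between 0.570 and 0.661 and every S. anglica array between 0.627 and 0.673, above the midpoint of 0.5.

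On the scale between the parents, both the hybrid and S. anglica lay nearer S. alterniflora. The mean position was 0.621 ± 0.034 (SD, n = 5 arrays) in the hybrid and 0.651 ± 0.021 in S. anglica. The difference of 0.0303 was within the spread between arrays (exact permutation test, two-sided, p = 0.135). For the 199 probes brighter in S. alterniflora, with chitinase and rbcL among them, the mean position was 0.716 in the hybrid and 0.651 in S. anglica. For the 283 brighter in S. maritima, such as PCNA and NHX1, it was 0.526 and 0.652. Simulated additive hybrids averaged 0.678 for the former (from 0.649 to 0.700) and 0.341 for the latter (from 0.316 to 0.364). With slide as a block the difference was 0.0530, or 0.0893 with slide fitted to the positions themselves (linear model, 95% interval 0.0536 to 0.125), but it was negative with the percentile over all probes (-0.00707), under normexp (-0.272), on the linear scale (-0.00429) and without 4 arrays that stood apart (-0.0131), so whether S. anglica lay nearer S. alterniflora than the hybrid did depended on these choices.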

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

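The tests on slides, scaling, background, S. maritima replicate 2 and the joint state of both genomes were chosen after the results were seen, whereas the splits of the arrays, the simulated hybrids and the brightness-matched sets were set down before their results. In groups of 5 arrays, an array was singled out when its gap to the nearest other exceeded 0.71 of the group's range, which chance brings about in roughly 1 in 20 groups. This held for 3 of 36 groups of array measures and 13 of 148 groups of named-gene signals.

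The share of spots well above background was 32.72% on S. maritima replicate 2 and 9.04% to 10.15% on the other S. maritima arrays. The median local background was 52 on hybrid replicate 3, against 42.5 to 45 on the others, and the SD of negative control spots was 445.9 on hybrid replicate 4, against 1.35 to 3.71. Single arrays stood apart in log2 signal for 13 named-gene groups. In S. maritima these were PCNA (AK071591) at 9.016 on replicate 1, the asparaginyl endopeptidase (AK058553) at 7.946 on replicate 2, the coixin-type protein (AK106275) at 9.775 and NADH dehydrogenase subunit 1 (AK064531) at 7.455 on replicate 3, and psbM (AK058861) at 15.07 on replicate 4. In S. alterniflora, dehydrin (AK109096) was at 5.284 on replicate 5. In the hybrid, dehydrin was at 5.749 and the peroxisomal membrane protein (AK100851) at 9.207 on replicate 3, and PGPD14 (AK104810) was at 7.087 and the protein kinase (AK070965) at 9.931 on replicate 4. In S. anglica, sucrose synthase 3 (AK099406) was at 9.274 on replicate 1, a chloroplast ribosomal RNA (AK059621) at 13.61 on replicate 2 and the transcription factor AK107555 at 6.629 on replicate 3. The departure from the midparent differed between S. anglica and the hybrid at 294 probes, by the direct limma comparison of both groups.

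Transcripts of the plastid genome were lower in S. anglica. Of 21 measured, 19 fell against the midparent, with a median of -1.73, and S. anglica lay below the hybrid in the mean over the set (-1.55 ± 0.73 against -0.37 ± 0.20, SD, n = 5 arrays, exact permutation test, two-sided, p = 0.00794). The tables argue against slides as the whole source, since the median was -1.41 with slide as a block, although it was only -0.46 within slide 3, where all tested probes had -0.30, and -2.56 within slide 4 against the hybrid. They argue against a fall of all probes of like brightness, since the lowest median of 10000 matched random sets was -1.50. A leaf state that lowers chloroplast genes of both genomes alike was also examined. Against the hybrid the plastid set fell further than the nuclear one (difference -0.90, exact p = 0.00794, and -0.63 ± 0.23, SE, p = 0.0232 with slide as a block in a linear model). Some nuclear probes stood at the floor in S. anglica and could fall no further (AK065247 and AK073283, both 2.76), so the order of the sets does not settle that question. Within slide 3, with a single S. anglica array, the order was the opposite, with a nuclear median of -0.84 and 24 of 24 negative, and with slide as a block the medians against the midparent were -1.41 and -1.16, and the nuclear set itself fell against the hybrid by 0.69 (linear model, p = 0.000905, against -0.28, exact p = 0.198, without the block), so a leaf state that lowers both sets may account for part of the fall. A lower abundance of plastid transcripts in these S. anglica leaves may remain as a hypothesis, with the wide range between its arrays (-0.99 and -0.61 on replicates 1 and 2, and -1.75 to -2.38 on replicates 3 to 5), leaf age and plant-to-plant differences untested.

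More probes lay below than above the midparent in S. anglica, with 26.02% of the 538 above. Slides as the whole source are argued against, since a slide block left 145 probes above and raised those below from 398 to 672 (17.75% above), and the median of all tested probes within slide 3 was -0.30. Background left in the signal is argued against, since a few units of background cannot move bright probes, and among the 442 probes with the brightest midparent 27.14% of 199 calls were above (95% binomial interval 21.09% to 33.88%). The same arrays gave 57.3% above in the authors' table. That table set S. maritima 2 lower than the other arrays (median probe-centred difference -1.84), which by itself lowers the midparent. Quantile normalization and median scaling also raised the share above, though not past an even split, so scaling stays open as a source. The excess of lower values could therefore come from the choice of scaling, and no biological reading of it was tested. Plastid genes do not hang on this, as their median stayed between -0.96 and -1.73 under all scalings tried.

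The hybrid and S. anglica both lay nearer S. alterniflora, with mean positions of 0.621 and 0.651. Selection of probes and the log2 scale are argued against for the mean over both directions, since the highest of 100 simulated additive hybrids reached 0.526. By direction, under the main scaling, S. anglica at 0.651 lay within the simulated 0.649 to 0.700 for probes brighter in S. alterniflora. For those brighter in S. maritima it lay above the simulated range (0.652, simulated up to 0.364), whereas the hybrid lay above both ranges (0.716 and 0.526). A shift of all values of an array moves these directions in opposite ways, and the split by direction was not computed under other scalings. It therefore does not settle on which probes the lean of S. anglica rests. Slides are argued against, since in a linear model of the positions with slide as a block the lower 95% limit was 0.583 for the hybrid and 0.672 for S. anglica, and so is the high S. maritima replicate 2, without which the lowest array stood at 0.572. Under normexp the S. anglica mean was 0.468, with large negative background estimates on some S. maritima and S. anglica arrays, whose part in this was not tested. A maternal lean of leaf expression may remain as a hypothesis, and a better match of S. alterniflora sequences to rice probes was not tested.

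Other splits of the same arrays were drawn 100 times for each count, the real one included, and for every count the share with as many probes was under 0.05. For the counts between 2 groups, other splits, which mix the slides, seldom gave as many probes. For the hybrid against S. alterniflora, however, another split gave more than the real one (346 against 252). Arrays on one slide resembled each other and so were not free to exchange. These splits therefore argue against chance for the counts between 2 groups without excluding it. For the counts against the midparent or outside both parents, the split groups mixed the parental species, which widens their spread. Those splits therefore do not decide whether chance gives such departures from an even mixture of the parents. None of the splits excludes slides, since deviations of arrays on one slide correlated (median r = 0.32, against -0.03 across slides). Only 1 split, the real one, gave as many probes for the parents (676, highest other 441), S. anglica against the midparent (538, 56), S. anglica against the hybrid (294, 175), the hybrid against S. maritima (458, 289), S. anglica against S. alterniflora (491, 256), S. anglica against S. maritima (729, 356) and the probes outside both parents in S. anglica (157, 22). For the hybrid against the midparent 2 splits did (96, highest other 360), for the hybrid against S. alterniflora 2 (252, 346) and for the probes outside both parents in the hybrid 2 (19, 23). The split with 360 put hybrid 3 with S. alterniflora 3 and 4, from slides 2 and 5, and hybrid 1 with S. alterniflora 1 and S. maritima 2, from slide 7, which points to a structure of the samples beside the groups. Under a slide block the hybrid counts were 92, 198 and 8, of which 51, 166 and 2 were the same probes, so for the hybrid's departures and transgressive probes slides stay open as a source of many calls.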

How the results depend on the processing

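Of the alternatives, the floor halved or doubled, each array's median or the local background subtracted, the 4 arrays left out and slide 7 left out were chosen after seeing the data. The 121 named-gene values were computed again under 38 other settings, 4571 values in total, of which 4162 kept direction and side of the threshold, 395 kept direction but no longer passed and 14 changed sign. Signal over background limits these results, since most rice probes stayed near background with Spartina RNA. Where no cause is named, the cause was not tested. Quantile normalization, median scaling, the floor halved or doubled, both other background subtractions and limma's trend with robust fitting kept every count within 1.5 times. The mean of all probes of a gene was not run, since each probe stands for its own cDNA.

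Leaving out 1 array at a time gave 611 to 714 probes for the parents, 40 to 137 for the hybrid against the midparent, 383 to 625 for S. anglica against the midparent, 194 to 350 for S. anglica against the hybrid, 202 to 272 for the hybrid against S. alterniflora, 392 to 521 against S. maritima, 363 to 547 for S. anglica against S. alterniflora and 608 to 776 against S. maritima. Probes outside both parents numbered 8 to 25 in the hybrid and 105 to 197 in S. anglica, the difference in position 0.0119 to 0.0417, and 108 to 120 of the named values passed. The hybrid's transgressive count was 8 without hybrid 1, 10 without hybrid 3, 9 without hybrid 5 and 10 without S. alterniflora 3 or 4.

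The percentile over all probes, which lies near background here, gave 19 probes for the hybrid against the midparent, 176 for S. anglica against the hybrid, 84 and 188 for the hybrid against S. alterniflora and S. maritima, 466 for S. anglica against S. maritima and 4 outside both parents in the hybrid. The position difference was -0.00707, 74 named values passed and 1 list did, the Calvin cycle in S. anglica against the hybrid (adjusted p = 0.0325). Against the midparent in S. anglica, AK059470 turned to 0.0615, AK101973 to 0.0177, AK058882 to 0.11 and AK061784 to 0.20, and AK061784 to 0.0514 against the hybrid.

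Normexp fitted strongly negative background means on 3 S. maritima, 2 S. anglica and 1 S. alterniflora arrays, which raises dim probes there by construction. It gave 299 probes for the parents, 14 and 79 for the hybrid and S. anglica against the midparent, 81 for S. anglica against the hybrid, 53 and 1158 for the hybrid against S. alterniflora and S. maritima, and 160 and 131 for S. anglica. Probes outside both parents were 2 and 34, the position difference -0.272, and 71 named values passed and so did 2 lists in 3 comparisons, ion transport between the parents (0.0492) and photosystems in S. anglica against the midparent and the hybrid (0.00309). Signs changed for AK101974 (-0.12) and AK100969 (-0.38) between the parents, AK109096 (-0.33) in the hybrid, AK060907 (0.11) and AK110832 (0.0576) in S. anglica against the midparent, and AK070738 (0.41), AK062058 (0.28), AK067850 (0.75) and AK073133 (0.0205) against the hybrid.

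The authors' table gave 40 probes for the hybrid and 267 for S. anglica against the midparent, 188 for S. anglica against the hybrid, 460 against S. maritima and 86 outside both parents. Without a filter on dim probes, which adds many tests, the counts were 17, 208, 57, 119, 220, 253 and 401 in the order of the plot of counts from the hybrid against the midparent on, 1 and 49 outside both parents, and 74 named values. With probes well above background on all 20 arrays only, fewer were tested, with 410 for the parents, 277 for the hybrid and 444 for S. anglica against S. maritima. Using only the arrays of the groups compared gave 60 for the hybrid against the midparent.

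With slide as a block, S. anglica departed from the midparent at 817 probes, 8 and 257 probes lay outside both parents in the hybrid and S. anglica, and the position difference was 0.0530, past the threshold in a linear model with slide. With scan day as a block, 39 probes departed in the hybrid and 8 lay outside both parents. On the linear scale the position difference was -0.00429. Without the 4 arrays (S. maritima 2, S. alterniflora 3 and 4, hybrid 3) the hybrid departed at 30 probes, differed from S. alterniflora at 142 and had 7 outside both parents, with a position difference of -0.0131. Without slide 7 these were 23 for the hybrid against the midparent, 132 for S. anglica against the hybrid and 5 outside both parents, with fewer arrays.

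At an adjusted p under 0.01, which is stricter by construction, the counts were 29, 298, 139, 157, 290 and 310 from the hybrid against the midparent to S. anglica against S. alterniflora, and 6 and 78 outside both parents. At 2-fold or more they were 243 and 191 for S. anglica against the midparent and the hybrid, 150 and 275 for the hybrid against S. alterniflora and S. maritima, 295 and 440 for S. anglica, and 10 and 85 outside both parents.

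The median over all tested probes moved with scaling. For S. anglica against the midparent it was -0.35, and -0.08 under quantile normalization, 0.03 in the authors' table and 0.37 with the percentile over all probes. After the median was subtracted, 0 of the 121 named values changed sign. The replicate numbers did not pair the samples (median correlation of same-numbered deviations -0.04, from -0.38 to 0.55, with 5 arrays closest to their own number). With the replicate block the counts were 659, 87, 542, 279, 241, 445, 472 and 708 in the order of the plot of counts, 20 and 148 outside both parents, and the position difference was 0.0246.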

Other observations

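The 3 sets of transcripts here, and the tests on them, were chosen after the data were seen, and the test of a maternal level of mitochondrial transcripts was set down after its values were known. The sets are word patterns on the descriptions, so membership rests on likeness to genes of other plants.

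Transcripts of the mitochondrial genome were low in the hybrid. Of 9 measured members, 6 fell against the midparent and 8 had negative values, with a median of -1.08. With slide as a block 3 fell, and without hybrid 3 also 3. The 6 included genes for subunits of NADH dehydrogenase, the entry complex of the respiratory chain, namely nad1 (AK064531 at -1.21 and AK062689 at -1.08), nad7 (AK063521, -1.02) and nad5 (AK058433, -1.16), as well as rps3 (AK064438, -1.36) and the large ribosomal RNA (AK061547, -1.35). Brighter probes with the same nad7 description did not pass (AK109589 at -0.37 and AK064513 at -0.30). The gene atp6 of the ATP synthase (AK064582) was at 0.26. As a set they fell more than other probes by cameraPR (adjusted p = 3.4e-08, and adjusted p = 0.0239 with an estimated correlation). The latter did not pass without S. maritima 1 (0.127), hybrid 3 (0.0562) or hybrid 4 (0.0673). The set holds AK064438, AK061547 and AK064531, which were already among the named falls of the hybrid, and it was not tested without them. The median was -1.01 with slide as a block, -1.16 within slide 6 and -1.10 within slide 7, and between -0.65 and -1.08 over all scalings. In S. anglica 6 of 9 fell as well, with a median of -0.79 (adjusted p = 0.0262, and 0.519 with an estimated correlation). With slide as a block 4 fell there, and the set did not pass (cameraPR adjusted p = 0.317).

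The median of plastid transcripts in the hybrid was -0.26 with 2 of 21 lower, and in S. anglica 19 of 21 passed as lower and all 21 were negative. Against other probes the plastid set fell in S. anglica with an adjusted p of 6.5e-12 against the midparent by cameraPR (adjusted p = 0.0493 with an estimated correlation). The latter is at the edge, and with 1 array left out it did not pass in 13 of 20 cases, up to 0.127 without S. maritima 1 and 0.0951 without S. alterniflora 5. Against the hybrid it had 16 of 21 lower, a median of -1.48 and an adjusted p of 2.48e-09, which was lost with an estimated correlation (adjusted p = 0.0890). The 24 measured nuclear genes for chloroplast proteins had a median of -0.84 in S. anglica against the midparent, with 12 lower and none higher (adjusted p = 0.00619, and adjusted p = 0.599 with an estimated correlation). Leaving out single arrays moved the plastid median between -1.50 (without S. anglica 3) and -2.10 (without S. anglica 2). Outside the named genes, 14 plastid probes still had a median of -1.44.

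Mitochondria are inherited from the maternal parent in most flowering plants, so mitochondrial transcripts in the hybrid and S. anglica may sit at the maternal and not at the middle level. Mean set levels were 0.27 ± 0.36 in S. maritima, -0.44 ± 0.34 in S. alterniflora, -0.76 ± 0.19 in the hybrid and -0.45 ± 0.19 in S. anglica (SD, 5 arrays each). The hybrid lay below S. maritima by -1.03 (exact permutation test, two-sided, p = 0.00794, adjusted p = 0.0317) and differed from S. alterniflora by -0.32 (exact p = 0.135). S. anglica lay below S. maritima by -0.71 (exact p = 0.0159, adjusted p = 0.0317) and differed from S. alterniflora by -0.01 (exact p = 0.984). On the scale from 0 (paternal) to 1 (maternal), the lowest of the 10 arrays stood at 0.637, and the means were 1.45 ± 0.27 and 1.01 ± 0.26. The parental arrays overlapped on this scale, with S. maritima 3 at 0.668 and S. alterniflora 3 and 4 at 0.443 and 0.512. A position of 0.637 therefore does not tell a maternal from a paternal array. The parental difference that sets this scale had an adjusted p of 0.0635 (exact p = 0.0317). S. anglica lay above the hybrid by 0.31 (exact p = 0.0397, adjusted p = 0.0635), and by 0.35 ± 0.19 (SE) with slide as a block (linear model, p = 0.0954). All 5 hybrid arrays lay past the maternal mean (1.15 to 1.83). A maternal level of mitochondrial transcripts may remain as a hypothesis, better met by S. anglica than by the hybrid, but a difference of the mitochondrial sequences in their match to rice probes would give the same picture and was not tested.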
